A study of Mus musculus with 12 samples.

How the data were processed

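CUT&RUN libraries for H3K27ac, H3K27me3 and H3K4me3 from mouse intestinal organoids treated with vehicle or 25 µM AA for 6 days were analysed, 2 libraries per group and mark. The labels do not say that the 2 libraries of a group came from separate cultures or animals. P-values thus measure at most the spread between these libraries, which may be technical. Fisher's, binomial and signed-rank tests count peaks, which share the 4 libraries of their mark, so their p-values do not measure that spread. The design text of the series speaks of organoids lacking a prostaglandin receptor and of a prostaglandin arm, while the labels of the samples used here name no genotype and no such arm; the genotype was left open. Rows named as control in the deposited table were taken as vehicle, the only group of each mark left for them.

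The deposited signal is a peak score, and the authors gave 1 score per peak and library for 2 peak sets per mark. Peaks came from SEACR and MACS2 on the mm10 build, per the submitters' processing notes; versions, the aligner and the scaling are not given in the sources used here. Tested on the values, score times peak length was a whole multiple of 1 step per library for 100% of the values below 1000 steps, within 0.1 step, as for a mean coverage per base scaled by 1 factor per library. The score divided by the step was used as the raw depth. Each mark's peaks were scored in its own 4 libraries.

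SEACR peaks were chosen as the main set before any test, and MACS2 peaks were added as an alternative after the data were seen. Genes were taken from a RefSeq table of the same build with 21896 protein-coding genes and no strand, so a gene end within 1 kb stood in place of the transcription start and starts were not told apart from ends. Other peaks went to the smallest gene body they overlapped or to the nearest gene end within 50 kb; these are assignments by distance only. Of the gene list symbols, 5 entries had no match.

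The test was limma 3.58.1 in R 4.3.3 (trend and robust) on log2(score + pseudocount), AA minus vehicle, with the deposited scaling, Benjamini-Hochberg adjustment and a threshold of 0.05. The pseudocount was the 5th percentile of the positive values of the mark: 0.0693 for H3K27ac, 0.0329 for H3K27me3 and 0.0253 for H3K4me3. A change is on that scale and understates the change of weak peaks. Gene lists, 25 of them, were tested with camera (preset correlation 0.01, then estimated) and fry on 1 peak per gene, the one with the highest mean (gene-end peaks only for H3K4me3). With an estimated correlation camera rests on the few libraries of the mark and has little power. A list that does not pass there is thus not shown to be unchanged. The interaction between marks was fitted over 8 libraries per pair of marks, since no peak was scored in all 12. Named genes are the 10 largest rises and 10 largest falls per mark among called peaks whose groups do not overlap, without predicted genes, up to 4 called members per list, and genes fixed in advance; a few that this rule names are not reported here. Tests, lists, this rule and most alternatives were fixed before the data were examined.

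The test was tried on simulated data, 10 draws of 200 changed peaks per mark. With an equal spread for all peaks, 4.78% (H3K27ac), 4.74% (H3K27me3) and 3.48% (H3K4me3) of calls were false at the 0.05 threshold. With a spread that followed the level as in the real libraries, 9.88%, 6.93% and 20.9% were false, and 3.68%, 5.3% and 6.43% when the trend was taken over the simulated mean in place of the noisy one. The test thus called more false peaks than its threshold states, by the noise of the mean of 4 libraries. It was kept because it had been fixed, with a threshold of 0.01 added as an alternative after this was seen; that gave 4.54%, 6.74% and 10.4% false. Changes of 2 on the log2 scale were found for 85.7%, 13.5% and 40.2% of the changed peaks, and changes of 1 for 26.5%, 1.2% and 15.9%. The simulated noise was independent between peaks, with no shift shared by the peaks of a library and no spread particular to a peak. The false shares in the real libraries were not measured and can be higher.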

Results

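Histone marks were profiled by CUT&RUN, in which an antibody directs a nuclease to cut and release the DNA next to a chromatin mark, in mouse intestinal organoids, which are 3-dimensional cultures grown from isolated crypts. The organoids had received vehicle or 25 µM arachidonic acid (AA), an omega-6 fatty acid that is the precursor of prostaglandins, for 6 days. There were 2 libraries per group for each of 3 marks, 12 in all: H3K27ac, found at active promoters and enhancers, H3K27me3, laid down by Polycomb repressive complex 2, and H3K4me3, found at active promoters. The tested peaks numbered 62547 for H3K27ac, 105301 for H3K27me3 and 58548 for H3K4me3. The median peak had a raw coverage of 1.95 to 2.76 fragments per base in the H3K27ac libraries and 1.19 to 1.85 in the H3K27me3 libraries. For H3K4me3 it was 3.38 and 2.35 in the vehicle libraries and 1.37 and 1.46 in the AA libraries, so single weak peaks rest on few fragments and the AA group was the shallower one. The Spearman correlation over peaks between libraries of 1 group was 0.81 (vehicle) and 0.72 (AA) for H3K4me3, 0.51 and 0.65 for H3K27ac, and 0.19 and 0.29 for H3K27me3. Libraries of different groups correlated about as well, from 0.64 to 0.82 for H3K4me3, 0.54 to 0.59 for H3K27ac and 0.12 to 0.23 for H3K27me3. AA replicate 2 of H3K4me3 stood apart, at 157.7 on a first principal component (48.8% of the variance) on which the other libraries lay between -74.1 and -13.5.

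The first comparison asked where H3K4me3 differed between AA and vehicle. The score at the gene end of Anxa1, an annexin gene of the fetal-like and regenerative epithelium, a state the intestine enters on injury, was 0.25 ± 0.0294 in vehicle and 1.1 ± 0.0347 in AA (SD, n = 2 libraries each), a change of 2.03 ± 0.21 on the log2 scale (SE, limma adjusted p = 3.88e-18). Msln, which encodes mesothelin, rose from 0.0598 ± 0.00916 to 0.376 ± 0.034 (SD, n = 2). The brush-border peptidase gene Dpp4 fell from 0.956 ± 0.0783 to 0.451 ± 0.087 and the glucose transporter gene Slc2a2 from 0.357 ± 0.0516 to 0.112 ± 0.0155 (SD, n = 2). Over all peaks, limma called 1710 at an adjusted p of 0.05, 904 higher and 806 lower. Of the 56 named genes past the threshold, 54 passed after centring, and 6 passed in each of the 4 fits without 1 library: Anxa1 (highest adjusted p 1.17e-05), Col4a2 (0.00492), Syt16, St3gal4, Vsig1 and Esrrg. The calls at Msln (0.0878), Dpp4 (0.759), Slc2a2 (0.884), Ereg (0.789) and Ptgs2 (0.884) ended in at least 1 of those fits.

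**Figure D1:**
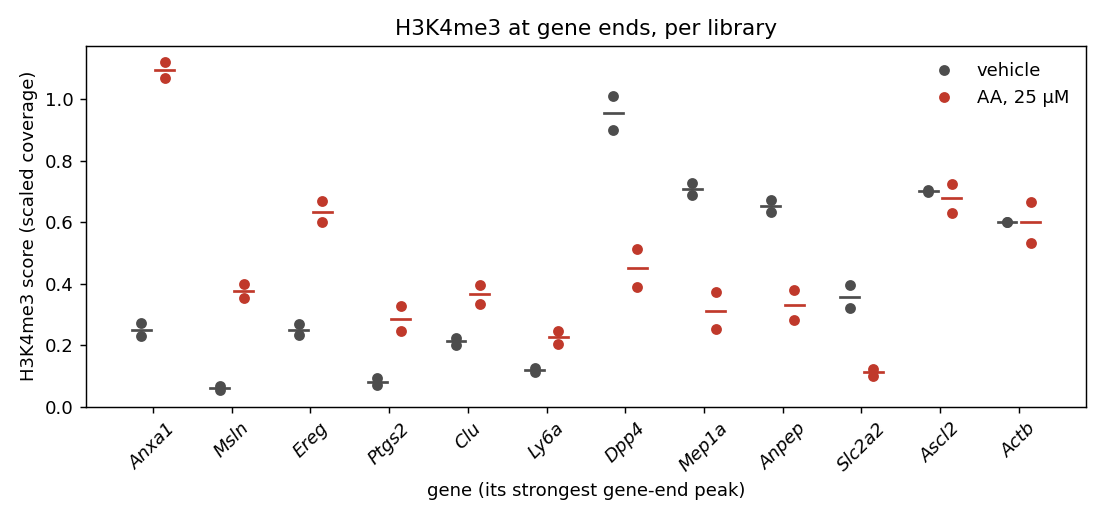
H3K4me3 score (scaled coverage per base) at the strongest gene-end peak of 12 genes; points are libraries (2 vehicle, 2 AA) and bars are group means. Anxa1 lies at 0.271 and 0.229 in vehicle and 1.12 and 1.07 in AA, Dpp4 at 1.01 and 0.9 in vehicle and 0.512 and 0.389 in AA, while Actb overlaps between the groups.

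Of 23 measured members of the fetal-like list, 9 rose, 0 fell and 14 did not pass, with a median log2 change of 0.72 against 0.18 for all genes. The count was 11 adjusted over the list alone. Besides Anxa1 and Msln, the EGF receptor ligand gene Ereg rose by 1.26 ± 0.25 (SE, limma adjusted p = 0.000163). Ptgs2, which encodes the cyclooxygenase that turns AA into prostaglandin, rose from 0.0814 ± 0.0148 to 0.286 ± 0.0582 (SD, n = 2; limma adjusted p = 0.0213). Clu (0.72, adjusted p = 0.187) and Ly6a (0.8, adjusted p = 0.313), both markers of the same state, did not pass in limma. The list was higher than other genes by camera with a preset correlation (adjusted p = 4.82e-05), and not with an estimated correlation (adjusted p = 0.815). With so few libraries the second form could hardly pass for any list. With the deposited scaling the estimated correlation was 0.32, above the preset of 0.01, so the preset p leaves out such co-variation of the members. After quantile normalization the estimated correlation was -0.012, below the preset, and the camera adjusted p was still 0.415, against 1.03e-06 preset. The estimated form therefore decides little here, and the preset p with the deposited scaling can be too small.

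YAP/TAZ targets, which respond to the effectors of the Hippo pathway, held 6 members that rose, 0 that fell and 12 that did not pass out of 18, and 9 rose and 1 fell adjusted over the list alone. Myof rose by 1.38 and Ptpn14 by 1.33, and the transcription factor gene Tead1 by 0.57. Camera gave an adjusted p of 0.00722 with the preset correlation (adjusted p = 0.815 with an estimated correlation of 0.55, 0.156 with the mean over all peaks of a gene). Among 25 targets of PPAR and fatty acid oxidation genes, 3 rose and 0 fell (8 adjusted over the list alone): the receptor gene Ppard by 0.64, the pyruvate dehydrogenase kinase gene Pdk4 by 0.81 and the acyl-CoA dehydrogenase gene Acadl by 0.6. That list had an adjusted p of 0.0493, and its call ended under the mean over all peaks (0.104), quantile normalization (0.139), MACS2 peaks (0.12) and without any 1 of the 4 libraries (0.0528 to 0.0693). The cell cycle list had 2 members that rose of 23, Top2a by 0.48 and Mcm5 by 0.46, with 7 adjusted over the list alone and a list adjusted p of 0.0284 (0.391 after quantile normalization, 0.104 with the mean over all peaks, 0.102 without vehicle replicate 2). For both lists the camera adjusted p was 0.815 with an estimated correlation, which was 0.52 for PPAR targets and 0.74 for the cell cycle list.

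In the enterocyte list 4 of 25 members fell and 0 rose, in the whole test and adjusted over the list alone. With Dpp4 and Slc2a2, the meprin gene Mep1a fell by 1.14 and the aminopeptidase gene Anpep by 0.94. The list was lower than other genes (camera adjusted p = 0.000158 preset, adjusted p = 0.815 with an estimated correlation of 0.54). After quantile normalization it passed with the preset correlation (camera adjusted p = 0.0097), and not with an estimated correlation (adjusted p = 0.649). The enteroendocrine list had a median of -0.5 over 13 members, of which 0 passed (adjusted p = 0.00122 preset, adjusted p = 0.815 with an estimated correlation, 0.236 after quantile normalization). The 54 developmental Polycomb targets had a median of -0.28, and 1 of them fell and 3 rose, Tbx3 (0.52) and Gata6 (0.44) among the rises. Their adjusted p was 9.09e-05 preset, 0.815 with an estimated correlation and 0.165 after quantile normalization. Fibroblast markers, included as another cell type, had a median of -0.74 over 11 members, 0 of them above 0, 0 called and 1 lower adjusted over the list alone, with an adjusted p of 0.000632 preset, 0.815 with an estimated correlation and 0.146 after quantile normalization. These lists lie at weak gene-end peaks, with median scores of 0.35 (enterocyte), 0.159 (enteroendocrine), 0.219 (Polycomb targets) and 0.136 (fibroblast), against 0.674 for all genes. With all H3K4me3 peaks in 10 bins by level, bins with median scores from 0.137 to 0.321 had median changes from -0.34 to -0.2. The falls of the enteroendocrine, Polycomb target and fibroblast lists were thus not separated from level, although the fetal-like list, at 0.289, rose. The enterocyte list, with a median change of -0.22, lies between the bins at 0.321 (-0.2) and 0.597 (0.13). Its fall was not compared with peaks of the same level, so it was not separated from level either.

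**Figure D2:**
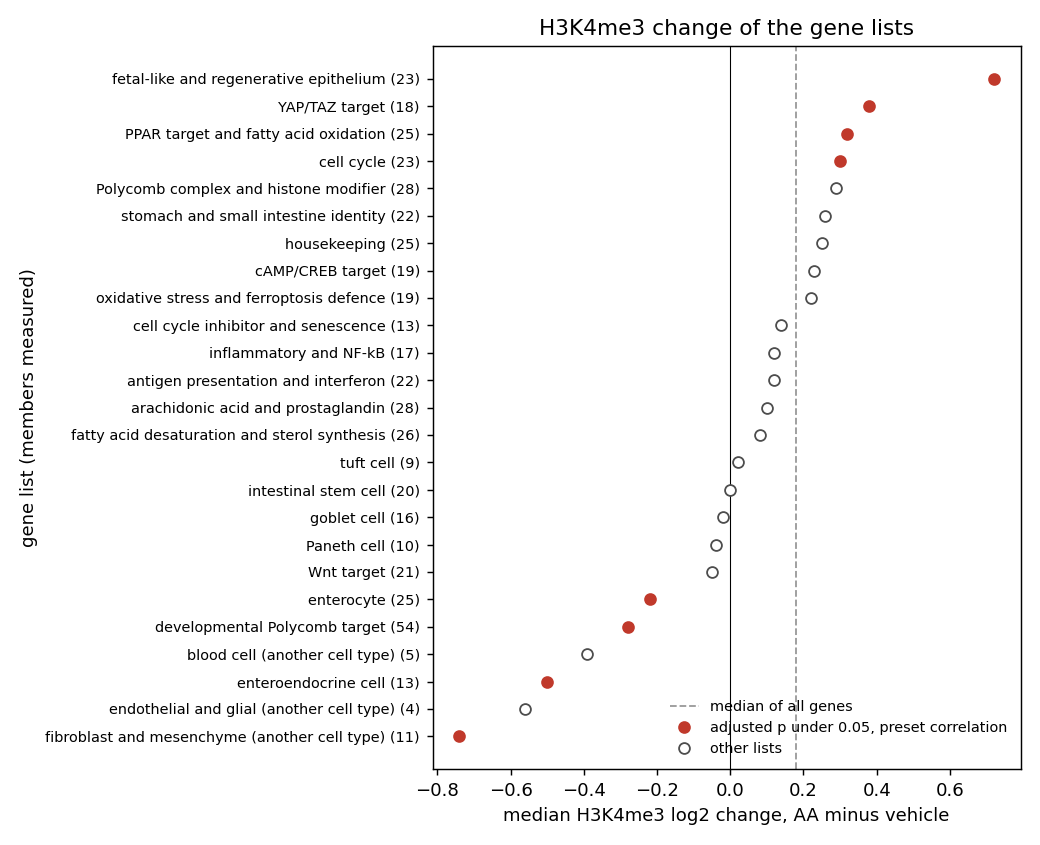
Median H3K4me3 log2 change (AA minus vehicle) of the 25 gene lists, with the number of measured members in brackets; filled points passed camera with a preset correlation, and the dashed line is the median of all genes. The fetal-like list lies at 0.72 and the fibroblast list at -0.74.

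The stem cell list (median 0, adjusted p = 0.146) and the Wnt target list (median -0.05, adjusted p = 0.101) did not pass with the deposited scaling, and were lower than other genes after quantile normalization with the preset correlation (adjusted p = 5.48e-06 and 0.0145). With an estimated correlation they did not pass (adjusted p = 0.815 each with the deposited scaling, 0.415 and 0.649 after quantile normalization). In the stem cell list 1 of 20 members rose, the adhesion receptor gene Cd44 by 0.6. Olfm4, a stem cell marker, was at 0.46 ± 0.0156 in vehicle and 0.292 ± 0.0115 in AA (SD, n = 2; limma adjusted p = 0.191), and the value at Ascl2 was -0.05, with the opposite sign (0.16) after centring. Lgr5 had no gene-end peak. Of 21 Wnt targets, Lef1 fell by 0.83 and the secreted Wnt inhibitor gene Notum by 0.88, and Cd44 rose. Centring ended the calls at Lef1 (-0.61, adjusted p = 0.0774) and Notum (-0.67, adjusted p = 0.0958) and kept Cd44 (adjusted p = 0.000113). The prostaglandin list held Ptgs2 (1.54) and the prostaglandin synthase gene Ptges2 (0.45) among its rises and the PGE2 receptor gene Ptger2 (-1.4) and Cyp2c55 (-1.04) among its falls. The change at Ptger4 was 0.35 (limma adjusted p = 0.126), and the list had a median of 0.1 (adjusted p = 0.256).

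The other lists did not pass camera with the deposited scaling. Among them the desaturation and sterol synthesis list (median 0.08, adjusted p = 0.386) was lower after quantile normalization with the preset correlation (adjusted p = 0.00473), and not with an estimated correlation (adjusted p = 0.826 as deposited, 0.684 after quantile normalization). The medians were 0.29 for Polycomb and histone modifier genes (adjusted p = 0.0663, 2 members higher and 8 adjusted over the list alone), 0.02 for tuft cell genes (0.0588), -0.04 for Paneth cell genes (0.104), -0.02 for goblet cell genes (0.377), 0.23 for cAMP/CREB targets (0.228), 0.22 for oxidative stress genes (0.22), 0.26 for stomach and intestinal identity factors (0.228) and 0.25 for housekeeping genes (0.177). They were 0.14 for cell cycle inhibitors (adjusted p = 0.564), 0.12 for antigen presentation (0.177), 0.12 for inflammatory genes (0.386), -0.39 for blood cell genes (0.146) and -0.56 for endothelial and glial genes (0.22). The demethylase gene Kdm6a was among the modifiers that rose, the glutathione genes Gsta1 and Gclc among those of oxidative stress, and Gata5 and Foxa1 among the identity factors. By fry, which tests a list against no change, the lowest adjusted p for a change in 1 direction was 0.387. For changes of members in either direction 14 of the 25 lists passed, the fetal-like list with the lowest adjusted p (0.00729).

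The largest rises of single peaks were at Col4a2 (2.98), a basement membrane collagen gene, Syt16 (2.9), Tnpo3 (2.81), Apob (2.79), St3gal4 (2.75), Mgat4a (2.72), Cxxc1 (2.7), Gcnt2 (2.69), Vsig1 (2.6) and Rbm6 (2.55). The largest falls were at Esrrg (-2.99), an orphan nuclear receptor gene, Pid1 (-2.78), Rai14 (-2.73), Prlr (-2.33), Slitrk3 (-2.29), Pcsk5 (-2.24), Cystm1 (-2.24), Zfp454 (-2.22), Gng11 (-2.22) and Fer (-2.22). The Col4a2 peak lies at a gene end on chromosome 8 from 11311126 to 11313865 and the Esrrg peak in the gene body on chromosome 1 from 187660541 to 187666549 (mm10). Of the peaks called higher, 70.1% were at a gene end, against 22.8% of those called lower (Fisher's exact test, two-sided, p = 1.79e-88, odds ratio 7.93). Of all tested peaks 24.7% were at a gene end, close to the share of the lower calls. The strongest of 10 bins of peaks by level held 601 of the 904 higher and 36 of the 806 lower calls, so place was not separated from level in this test.

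The number of calls and the direction of the excess varied with the scaling, the peak set and single libraries. Centring each library on its median, which removed a shift of -0.21, gave 5557 higher and 549 lower (91% higher, against 52.9% as deposited), centring on the median of the strongest 25% of peaks gave 1496 higher and 3950 lower, and quantile normalization 41.4% higher. MACS2 peaks gave 1907 higher and 397 lower, and the strongest 25% of peaks 1471 and 502. Without vehicle replicate 1 or 2 limma called 36 or 32 peaks, 33 and 30 of them higher. Without AA replicate 1 it called 8478 (2974 higher, 5504 lower), without AA replicate 2 it called 8903 (6834 higher, 2069 lower), and without trend and robust 0, with 9469 peaks at an unadjusted p under 0.05 as tested here. In simulated libraries with 200 changed peaks whose spread followed the level, 20.9% of the H3K4me3 calls were false at the 0.05 threshold (a mean of 15.4 unchanged peaks called per draw). The simulation had no shifts shared by the peaks of a library, so the false share of the real calls can be higher. The 0.01 threshold left 540 calls in the real libraries.

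**Figure D3:**
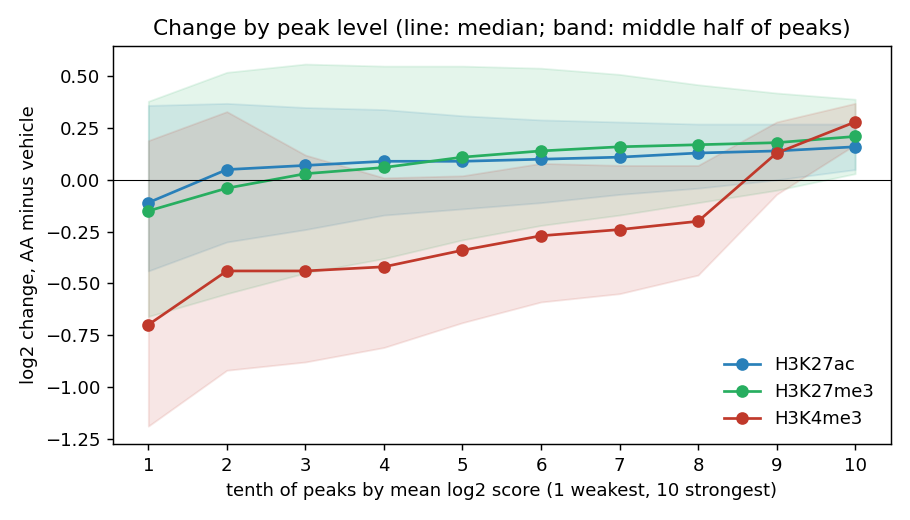
Median log2 change (AA minus vehicle) over 10 equal bins of the peaks of each mark ordered by mean log2 score, with the interquartile range as a band. H3K4me3 goes from -0.7 in the weakest bin to 0.28 in the strongest, H3K27ac from -0.11 to 0.16 and H3K27me3 from -0.15 to 0.21.

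The second comparison asked where H3K27me3 differed. The mark fell at the gene end of Clu, which encodes clusterin, from 0.279 ± 0.134 to 0.0578 ± 0.03 (SD, n = 2; change -1.75 ± 0.4, SE; limma adjusted p = 0.0145), on chromosome 14 from 65968322 to 65968723. It also fell at Hes6 (-2.71), a Notch pathway repressor gene, Eif2b2 (-2.09), Zfand2a (-1.77), Phlpp2 (-1.67), Klhl36 (-1.63), Rbpms (-1.5), Unc80 (-1.5), Myl12b (-1.4) and Vmn2r91 (-1.36). It rose at the genes of the secretory lineage factor Atoh1 from 0.356 ± 0.00955 to 0.484 ± 0.049, the tuft cell factor Pou2f3 from 0.101 ± 0.00888 to 0.248 ± 0.0272 and, in the gene body, the fatty acid receptor Ppara from 0.0712 ± 0.0189 to 0.268 ± 0.0178 (SD, n = 2). In all, limma called 574 peaks, 524 higher and 50 lower. Of the 43 named genes past the threshold, 6 passed after centring, and 2, Myl12b and Jarid2, passed in each of the 4 fits without 1 library. At both, H3K4me3 was also called lower in the overlapping peak (-0.52, adjusted p = 0.0145, and -0.51, adjusted p = 0.0195). Centring ended the calls at Clu (-1.86, adjusted p = 0.0918), Hes6 (-2.82, adjusted p = 0.0805), Atoh1 (0.3 against 0.41 as deposited, adjusted p = 0.47), Pou2f3 (0.96 against 1.07, adjusted p = 0.311) and Ppara (1.43 against 1.54, adjusted p = 0.115), while each value moved only by the shift of -0.11 that centring applied. Clu did not pass in any fit without 1 library (0.0841 to 0.974).

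Single list members that rose were Notum (0.82) and Sp5 (0.42) among Wnt targets, Lyz2 (1.48) and Defa24 (0.67) among Paneth cell genes, Tslp (1.16) with Pou2f3 (1.07) among tuft cell genes, Insm1 (0.43) among enteroendocrine genes, and the prostaglandin transporter gene Slco2a1 (1.04). Asap1 (1.57) and Foxf2 (0.31) rose among YAP/TAZ targets, Prdm1 (0.69) and Nr5a2 (1.62) among intestinal identity factors, H2-DMa (1.09) in antigen presentation, Insig1 (0.32) in sterol synthesis and the mesenchymal gene Vim (0.51). Of the Polycomb and histone modifier genes, Cbx8 (0.46) and Rbbp7 (0.95) rose and Jarid2 fell by 0.86. The largest rises were at Cox10, listed at 0 in both vehicle libraries, Esrrg (2.54), Cyp2c69 (2.49), Zscan4d (2.42), Trp63 (2.34), Krt10 (2.25), Ssh2 (2.16), Fmod (2.12), Coq8a (2.11) and Prex1 (2.06).

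Of 60 developmental Polycomb targets, 3 rose and 0 fell, and 20 rose adjusted over the list alone. The domain at Hoxa9 went from 0.514 ± 0.0431 to 0.606 ± 0.0138 (SD, n = 2; change 0.23, limma adjusted p = 0.0207), with Hoxd8 and Pax3 at 0.25 each. These changes were near the median of all genes, 0.2. Centring ended the calls at Hoxa9 (0.12, limma adjusted p = 0.75), Hoxd8 (0.14, adjusted p = 0.723) and Pax3 (0.14, adjusted p = 0.717). The developmental Polycomb list was the only 1 of the 25 lists past camera's threshold (adjusted p = 0.000594 preset, adjusted p = 0.885 with an estimated correlation). Its members had a median of 0.16 against 0.2 for all genes, so the median lay below the other genes while camera gave a rise, and after quantile normalization camera gave the opposite direction (adjusted p = 0.535). The fetal-like list, with Clu as the 1 member called of 14, had a median of -0.13 (adjusted p = 0.133). Lgr5 (0.52), Olfm4 (1.1) and Ascl2 (0.87), read at peaks 7251, 10484 and 13874 bp from the gene end, and Cdkn2a (0.06) did not pass. The gene-end peaks of Lgr5, Olfm4 and Ascl2 had H3K27me3 changes of 0.91, 1.01 and 0.11.

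The medians of the lists that did not pass were 0.48 for enterocyte (adjusted p = 0.532), 0.35 for enteroendocrine (0.133), 0.21 for goblet (0.531), 0.24 for Paneth (0.985) and 0.2 for tuft cell genes (0.985). They were 0.33 for stem cell genes (adjusted p = 0.985), 0.2 for Wnt targets (0.707), 0.17 for YAP/TAZ targets (0.718), 0.15 for prostaglandin genes (0.753), 0.14 for cAMP/CREB targets (0.985), 0.15 for PPAR targets (0.745), 0 for sterol synthesis (0.81) and -0.17 for oxidative stress genes (0.363). For cell cycle genes the median was 0.44 (adjusted p = 0.985), for cell cycle inhibitors 0.24 (0.985), for antigen presentation 0.39 (0.99), for inflammatory genes 0.06 (0.707), for Polycomb and histone modifier genes 0.18 (0.985) and for identity factors 0.29 (0.531). Fibroblast genes were at 0.05 (adjusted p = 0.826), blood cell genes at 0.31 (0.753), endothelial and glial genes at 0.16 (0.985) and housekeeping genes at 0.53 (0.531). The lowest adjusted p by fry was 0.222 for a change in 1 direction and 0.0263 for changes in either direction, for which 10 lists passed. A gene end held 40.6% of the peaks called higher and 34% of those called lower (Fisher's exact test, two-sided, p = 0.45), against 9.2% of all tested peaks.

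The excess of rises moved with the scaling and with the libraries and peaks kept: 91.3% of calls were higher as deposited, 59.5% of 79 calls after centring, which removed a shift of 0.11, and 51.2% of 164 after quantile normalization. Leaving out vehicle replicate 1 or 2 gave 23 higher and 21 lower or 35 and 16, and AA replicate 1 or 2 gave 41 and 32 or 49 and 41. The strongest 25% of peaks gave 76 and 20, a depth of 3 or more 105 and 21, MACS2 peaks 10 calls (9 of them lower), and limma without trend and robust 0, with 9888 peaks at an unadjusted p under 0.05 as tested here; in the simulation 6.93% of calls were false and 13.5% of changes of 2 on the log2 scale were found.

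The third comparison asked where H3K27ac differed. It rose at a peak assigned to Pdk4, a PPAR target, from 0.162 ± 0.0212 to 0.41 ± 0.0437, and at one assigned to Fabp1, the fatty acid binding protein gene of the enterocyte, from 0.139 ± 0.00634 to 0.351 ± 0.102 (SD, n = 2). It also rose at Sqle (1.03), a sterol synthesis enzyme gene, Saa3 (0.96), an acute phase gene, Arhgef17 (0.9) and Agr2 (0.63), a goblet cell gene. The largest rises were at Slc35f3 (1.61), Ppp1r15b (1.48), Ggt1 (1.32), Aldh1a1 (1.28), Dcaf5 (1.27), Galk2 (1.22), Rhobtb1 (1.19), Ripor3 (1.16), Ppp1r3e (1.13) and Dpy19l1 (1.11). The largest falls were at Ank (-1.54), Zdhhc20 (-1.24), Endod1 (-1.23), Rex2 (-1.21), Gtf3a (-1.18), Vmn1r77 (-1.17), Fgf5 (-1.15), Grb2 (-1.05), Eepd1 (-1) and Tcstv3 (-0.92).

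In all, limma called 125 peaks, 97 higher and 28 lower, and 0 of the 25 lists passed camera. The fetal-like list had a median of 0.27 over 19 members (adjusted p = 0.323), with 0 called and 4 adjusted over the list alone. Oxidative stress genes (median 0.27), PPAR targets (0.2) and tuft cell genes (-0.04) shared the lowest adjusted p of 0.239, and by fry for a change in 1 direction it was 0.357 (adjusted p = 0.993 for every list with an estimated correlation). By fry for changes in either direction only the housekeeping list passed (adjusted p = 0.00115). The other medians were 0.14 for stem cell genes (adjusted p = 0.975), 0.2 for YAP/TAZ targets (0.8), 0.1 for Wnt targets (0.896), 0.09 for enterocyte (0.986), 0.13 for goblet (0.896), -0.02 for Paneth (0.567) and 0.12 for enteroendocrine genes (0.975). They were 0.18 for prostaglandin genes (adjusted p = 0.954), 0.12 for cAMP/CREB targets (0.954), 0.14 for sterol synthesis (0.8), 0.11 for cell cycle genes (0.986), 0.08 for cell cycle inhibitors (0.8), 0.06 for antigen presentation (0.8), 0.23 for inflammatory genes (0.408), 0.09 for Polycomb and histone modifier genes (0.982), 0.13 for developmental Polycomb targets (0.896) and 0.18 for identity factors (0.448). Fibroblast genes were at 0.16 (adjusted p = 0.986), blood cell genes at 0.15 (0.53), endothelial and glial genes at 0 (0.436) and housekeeping genes at 0.19 (0.436). Anxa1 (0.54), Ly6a (0.58), Lgr5 (0.24), Olfm4 (-0.07) and Cpt1a (0.27) did not pass. The Lgr5 peak lies in the gene body and the Ly6a and Olfm4 peaks 1691 and 9139 bp from the gene end, while the gene-end peaks of Lgr5, Ly6a and Olfm4 had H3K27ac changes of 0.13, 0.09 and 0.28. Of the peaks called higher, 32% were at a gene end, against 3.6% of those called lower (Fisher's exact test, two-sided, p = 0.00132, and p = 0.0592 with gene ends taken to 3 kb) and 20.3% of all tested peaks. These calls were not stable: limma called 67 peaks without vehicle replicate 1, 35 without AA replicate 2 (6 higher and 29 lower) and 0 without AA replicate 1, and 0 in the strongest 25% of peaks, at a mean raw depth of 3 or more, with MACS2 peaks and without trend and robust, against 4821 SEACR and 694 MACS2 peaks at an unadjusted p under 0.05. Of the 26 named genes past the threshold, Pdk4 and Fabp1 included, 23 passed after centring and 0 in each of the 4 fits without 1 library. Quantile normalization moved the share of higher calls from 77.6% to 55.8%, and 9.88% of calls were false in the simulation. Centring on the median of the strongest 25% of peaks turned the excess around, with 39 higher and 62 lower.

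The typical signal of each mark was compared next. The median score was 0.182 ± 0.00915 in vehicle and 0.195 ± 0.0117 in AA for H3K27ac, 0.106 ± 0.0019 and 0.117 ± 0.00747 for H3K27me3, and 0.176 ± 0.00407 and 0.149 ± 0.000965 for H3K4me3 (SD, n = 2). The log2 ratio of the medians was 0.1, 0.14 and -0.25 and that of the summed scores -0.04, 0.08 and 0.07; a single peak held up to 20.7%, 29.7% and 20.8% of the sum. The exact two-sided permutation p of the medians was 0.67, 0.33 and 0.33, and 0.33 is the smallest that 2 against 2 libraries can give.

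The last comparison set the marks against each other at gene ends. Each mark's own strongest gene-end peak of a gene was used, so the peaks of 2 marks need not overlap. Rbpms lost H3K27me3 (-1.5) and gained H3K4me3 (1.23), while the fatty acid transporter gene Slc27a2 gained H3K27me3 (1.86) and lost H3K4me3 (-1.14), as did Notum (0.82 and -0.88) and Snai2 (0.61 and -1.74). Slc27a2 and Snai2 were chosen after their values were seen, and their calls were not refitted under the alternatives. At Notum both calls ended after centring (H3K27me3 0.71, adjusted p = 0.137; H3K4me3 -0.67, adjusted p = 0.0958), and the H3K27me3 call passed in 0 of the 4 fits without 1 library. Of 26 genes called in both marks, 24 changed in opposite directions and 2 in the same. Across 4351 genes, which are not independent replicates, the changes of these 2 marks had a Spearman correlation of -0.24 (Pearson -0.22). For H3K27ac and H3K4me3 the correlation was positive (Spearman 0.14, Pearson 0.17, 9372 genes), and all 5 genes called in both, S100a6, S100a1, Anxa13, C1galt1 and Wdr75, changed in the same direction. H3K27ac and H3K27me3 had a Spearman correlation of -0.13 over 2328 genes, with the opposite sign (0.04) in genes above the median of both marks. The limma interaction passed for 172 genes for H3K27me3 against H3K4me3, Clu (-1.75 against 0.72, adjusted p = 0.0391) and Olfm4 (1.01 against -0.61, adjusted p = 0.0351) among them. For H3K27ac against H3K4me3 it passed for 25 genes, with Anxa1 among them (0.54 against 2.03, adjusted p = 0.0212). For H3K27ac against H3K27me3 it passed for 2 genes, Tmem125 and Fam234b. At Tmem125 the H3K27ac change was 0.51 at its own gene-end peak. It was -0.44 in the peak overlapping the H3K27me3 peak, where H3K27me3 changed by -0.33. Pseudocount, range of scores and spread differ between marks, so a smaller log2 change in 1 mark was not told apart from its scale. With each library centred, 909 genes passed for H3K27ac against H3K4me3. The signed H3K27ac change minus the signed H3K4me3 change was above 0 for 32 and below 0 for 877 (14 and 11 as deposited). A difference above 0 can come from a fall of H3K4me3, as at Pbld1 (H3K27ac 0.31, H3K4me3 -1.35, as deposited). For H3K27me3 against H3K4me3, 182 genes passed after centring. The H3K27me3 change minus the H3K4me3 change was above 0 for 50 and below 0 for 132 (105 and 67 as deposited). With the replicate number as a block in the fit the counts were 69 for H3K27ac against H3K4me3 and 0 for H3K27me3 against H3K4me3. For H3K27ac against H3K27me3 the block also left 0.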

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

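The false share in simulation, low depth and 2 libraries per group limit every count of peaks. MACS2 peaks, a raw depth of 3 or more, centring on the strongest 25% of peaks, the 0.01 threshold, quantile normalization of lists and its estimated correlation were chosen after the data were seen. Where not stated, the cause was not tested. The filter alternative gave the main values, since the file assigns peaks to marks, and a model over all 12 libraries was not run.

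H3K4me3 (1710 calls) gave 6106 after centring, 5446 after centring on the strongest 25% (1496 higher, 3950 lower), 3078 at a threshold of 0.1, 540 at 0.01, 0 without trend and robust, and 32 to 8903 without 1 library. H3K27me3 (574) gave 164 after quantile normalization, 79 after centring, 179 after centring on the strongest 25% (73 higher, 106 lower), 96 in the strongest 25%, 126 at a depth of 3 or more, 51 with 10 times the pseudocount, 997 at 0.1, 253 at 0.01, 10 with MACS2 peaks, 0 without trend and robust, and 44 to 90 without 1 library. H3K27ac (125) gave 64 with 10 times the pseudocount, 241 at 0.1, 54 at 0.01, 0 in the strongest 25%, at a depth of 3 or more, with MACS2 peaks and without trend and robust, and 0 to 120 without 1 library. Of the named genes' and lists' values, 125 were no longer past the threshold without trend and robust, 102 to 107 without a vehicle library and 65 to 70 without an AA library. Without 1 library a group holds a single one, assumed to vary like the other group.

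The log2 odds ratio of H3K27ac gene ends was 1.62 within 3 kb. The typical H3K4me3 signal moved to -0.334 with both peak sets. With an estimated correlation 0 lists passed for H3K27me3 and 0 for H3K4me3, against 1 and 8, and likewise 0 and 0 after quantile normalization. With the mean over all peaks of a gene 5 passed for H3K4me3, 1 for H3K27ac and 0 for H3K27me3, which also had 0 after centring, quantile normalization or with MACS2 peaks and 0 to 2 without 1 library. The signed -log10 p of the developmental Polycomb list in H3K27me3 was -1.07 after quantile normalization and -0.0217 with MACS2 peaks. Correlations between marks moved to 0.12 (H3K27ac and H3K4me3), -0.36 (H3K27me3 and H3K4me3) and 0.04 (H3K27ac and H3K27me3, reversed) in genes above the median of both marks, and to -0.18 for H3K27me3 and H3K4me3 within 3 kb. Interaction calls for H3K27ac against H3K4me3 were 909 after centring.

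The replicate block gave 280 calls for H3K27ac, 857 for H3K27me3 and 2522 for H3K4me3, and interaction calls of 69 for H3K27ac against H3K4me3, 0 for H3K27me3 against H3K4me3 and 0 for H3K27ac against H3K27me3. Deviations of same-numbered libraries from their group means had correlations of 0.0085, 0.0025 and -0.0023 within the marks. At this low depth the noise of single libraries could hide a pairing, and pairing between marks was not tested. Whether the numbers pair the libraries thus stays open.

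The genes whose sign reversed had not passed. Without 1 library they lay, lowest to highest, as given in brackets. For H3K4me3 they were Ascl2 (0.16 centred; -0.15 to 0.05) and Actb (0.2 centred; -0.17 to 0.14). For H3K27ac they were Olfm4 (-0.16 to 0.02) and Ptgs2 (-0.35 to 0.94). For H3K27me3 they were Anxa1 (-0.09 quantile, -0.11 centred on the strongest 25%; -0.01 to 0.23), Ptgs2 (-0.21 to 1.7), Ptger4 (-0.85 to 0.19) and Cdkn2a (-0.13 quantile, -0.05 centred, -0.17 centred on the strongest 25%; -0.01 to 0.13).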

Other observations

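The tests of explanations here were chosen after the results were seen. Chromosome X held 23.2% of the H3K27me3 peaks, against 1.4% of the H3K27ac peaks and 2.8% of the H3K4me3 peaks, and its H3K27me3 peaks had a median change of 0.06, against 0.15 on the other chromosomes. At the ribosomal DNA repeat on chromosome 17 (39842859 to 39848841), a region whose reads come from many copies, H3K27me3 scores were 6.69 and 6.8 in vehicle and 3.41 and 3.71 in AA, and H3K4me3 scores 9.17 and 8.58 against 6.76 and 7.02. At peaks called higher in H3K27me3, 106 of the 301 overlapping H3K4me3 peaks lay above the median change of all H3K4me3 peaks, and 33 were called lower.

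H3K4me3 was higher at the fetal-like list with the preset correlation, but not with an estimated correlation (adjusted p = 0.815, and 0.415 after quantile normalization), a test with little power here. The estimated correlation with the deposited scaling was 0.32, above the preset of 0.01, so the preset p can be too small. A different signal over background in the AA libraries that moved only the whole distribution would vanish when all libraries are given the same one. The list median was then 0.83. A difference that varies with place need not vanish, and median H3K4me3 changes were 0.15 at gene ends, -0.32 in gene bodies and -0.31 between genes. A different signal over background therefore stays open. More fibroblasts in the AA cultures would raise fibroblast genes, and their median was -0.74, with Col1a1, the collagen gene abundant in such cells, at 0.559 ± 0.104 in vehicle and 0.531 ± 0.106 in AA (SD, n = 2). That list has a median score of only 0.136, and the bin of H3K4me3 peaks at 0.137 had a median change of -0.34. After quantile normalization its median was -0.4 (camera adjusted p = 0.146, preset). Its fall therefore cannot exclude more fibroblasts. A treatment effect stays open as a hypothesis. Chance is not settled either: 2 against 2 libraries make 3 splits, too few for a share under 0.05, and 1 split, the real one, reached 1710 H3K4me3 calls, with 0 the highest of the others (574 against 6 for H3K27me3, 125 against 7 for H3K27ac).

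The H3K4me3 change rose by 0.61 on the log2 scale from the fifth to the tenth of 10 bins of peaks ordered by level. The shallower vehicle library minus the deeper one gave -0.0049 over the same span. That does not settle the lower depth of the AA libraries. The vehicle libraries had median raw depths of 3.38 and 2.35, both above the 1.37 and 1.46 of the AA libraries. A different signal over background cannot be told apart from the treatment: the log2 ratio of the strongest bin to the fifth was 2.52 and 2.49 in vehicle and 3.17 and 3.19 in AA, a gap of 0.65 that follows the groups. From the weakest bin to the fifth the span was 0.37, while libraries of 1 group differed by 0.72 (vehicle) and -0.68 (AA).

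Peaks lower in H3K27me3 were weighed against fewer copies of the DNA in the AA cultures, which would lower every mark by a like amount, and against a lower background, with each overlapped peak set against the median change of its mark's peaks of the same place and level. At gene ends fewer copies could not be settled. The H3K4me3 change lay above 50% of the H3K27me3 change by a median of 0.9 (exact signed-rank test, two-sided, p = 0.00209, 17 peaks) and the H3K27ac change by 0.63 (exact p = 0.0391, 8 peaks), although 4 of the 17 fell by that share in H3K4me3. The peaks were chosen for their H3K27me3 fall, which inflates that fall, so the gap can come in part from the choice. Against matched peaks the median H3K4me3 change was 0.05 and the median H3K27ac change -0.19. A lower background cannot be told apart from a change of the mark there, since 7 of 17 H3K4me3 peaks (exact binomial p = 0.629) and 7 of 8 H3K27ac peaks (exact p = 0.0703) lay below the median and its size was not measured. Away from gene ends the values went with both explanations. The H3K4me3 change differed from 50% of the H3K27me3 change by a median of -0.03 (exact signed-rank p = 0.831). Below the median lay 22 of 29 H3K4me3 peaks (exact binomial p = 0.00813) and 22 of 24 H3K27ac peaks (exact binomial p = 3.59e-05). All peaks of a mark share its 4 libraries and are not independent replicates. The p-values of this paragraph therefore do not measure the spread between libraries. A treatment effect on the mark stays open in both places, as it was not tested apart from these.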
